A study of Mus musculus with 16 samples.

How the data were processed

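Transcript abundance was measured by RNA sequencing of the CA1 subfield of the hippocampus in 16 mice, 8 with the Fmr1 knockout (Fmr1-KO) and 8 wild type (WT, given as C57BL/6), all used as yoked controls in an active place avoidance task, per the labels. RNA was isolated with a Maxwell 16 LEV kit and sequenced on an Illumina HiSeq platform, per the labels' protocols. The submitters' processing notes name FastQC, cutadapt, kallisto and DESeq2. Their versions, the order of the steps, the genome build and the transcript index are not given in the sources used here. One table per library was deposited, in the column layout that kallisto writes, with 111706 transcripts named by GENCODE mouse identifiers.

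The deposited estimated counts are reads assigned to each transcript by a probabilistic model, so they can be fractional where transcripts share sequence. The deposited TPM values are relative transcript abundances scaled by effective length within each library by the authors' quantification, and they hold no information on depth. The deposited files also give the length and effective length of each transcript. An estimate for a gene that shares sequence with pseudogenes or close copies, such as ribosomal protein genes, the mitochondrially encoded genes or the pair Hspa1a and Hspa1b, depends on how reads were divided between the copies and is uncertain for that reason.

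Estimated counts were summed over the transcripts of each gene symbol as the files pair them (46403 symbols, of which 83 cover more than 1 gene identifier) and rounded to whole numbers. Positions came from the GENCODE M21 annotation of GRCm38, joined by gene identifier without its version, which gave a position for 45918 symbols. Group and animal were taken from the labels, and the replicate numbers used here follow the order of the labels and pair nothing. The labels give a number and a letter for each animal, so the libraries were read as separate animals, with up to 2 animals of a genotype sharing a number.

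Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM normalization, filterByExpr defaults with a minimum count of 10, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are TMM-normalised CPM (counts scaled to a common library size), given as mean ± SD. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. Transcripts were tested likewise. Fold changes are Fmr1-KO over WT. Lists of genes were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted over 20 gene lists and, as a separate family, over the 13 of 16 cell type marker lists that kept at least 3 tested genes. The marker lists for CA2 pyramidal cells, meningeal fibroblasts, and choroid plexus and ependyma kept fewer. Single values were compared by two-sided exact permutation tests in SciPy 1.17.1.

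The gene and marker lists, the tests of the comparisons, the rule for naming genes and the alternatives, apart from those said to be added later, were fixed before the data were examined. The rule takes Fmr1, up to 15 genes with the largest rise and up to 15 with the largest fall among those past the threshold, the 5 genes with the smallest p in a direction where fewer than 5 passed, and up to 4 members with the smallest p from each list. Not all of the list members so selected are named. The list of mRNAs bound by the Fmr1 protein is a part of what has been reported, chosen from memory. A list of 17 markers of dividing cells and newborn neurons was added after the Ccnd2 result, before the values of its members were looked up, and serves only in the closing observations. For the 8 gene lists past the threshold, random lists were drawn from the 50 nearest genes in length, GC content and abundance. Random lists do not share the correlation of co-regulated genes, so percentiles among them overstate how far a list stands apart. The genes eligible were all those outside the list itself, a choice made after a first result from a narrower pool had been seen, and the bars for excluding a linked segment near Ccnd2 and a loss of dividing cells were raised after the values were seen, the latter so that at least 0.8 of the markers had to be tested.

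Total estimated counts ranged from 515103 to 3275003 per library. WT replicates 3 and 6 held 878484 and 515103, and an alternative without both was added after the depths were seen. Other alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors, library totals, other filters, limma-voom with quality weights, log2(TPM + 1) and log2(TPM + 0.1), length-scaled TPM counts, the letter of the animal label as a covariate, its number as a random effect, 1 surrogate variable from sva 3.50.0, a threshold of 0.1 and the omission of each library in turn. Counts were simulated from the means, depths and dispersions of the 16 libraries (11235 genes tested). The same test recovered 28.4% of 67 genes changed 1.5-fold, 55.2% of 67 changed 2-fold and 89.4% of 66 changed 4-fold, with 5 false calls. These genes were changed together in 1 simulation. The adjustment is stricter where fewer genes change, so the rates overstate recovery in a comparison with few changed genes. A simulated shift of 1 list was recovered, and 0 unshifted lists passed the threshold. The simulated genes varied independently of one another, so this does not show how often lists of correlated genes pass by chance.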

Results

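The transcriptome of the CA1 subfield, the output layer of the hippocampus proper, was measured in 8 mice lacking Fmr1 and in 8 WT mice. Fmr1 encodes FMRP, an RNA-binding protein that represses translation and whose loss underlies fragile X syndrome. The mice were yoked controls of an active place avoidance task, and the series asks how the CA1 transcriptome differs between the genotypes. Genotype was the only factor in the labels. The WT mice are given as C57BL/6, and the labels do not say whether the genotypes were littermates. The p-values measure the spread between samples, each labelled with an animal of its own.

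Depth was low and uneven. Fmr1-KO libraries held 1480966 to 2979481 estimated counts. WT libraries held 2126632 to 3275003, except WT replicate 3 with 878484 and WT replicate 6 with 515103. These last libraries also differed in composition. Their 10 largest genes took 10.35% and 31.59% of the counts, against 3.73% to 6.06% in the other 14 libraries, and protein-coding transcripts took 80.67% and 58.38%, against 87.59% to 91.8%. Their median Spearman correlation with the other libraries, across genes, was 0.813 and 0.864, against at least 0.932 for every other library.

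**Figure D1:**
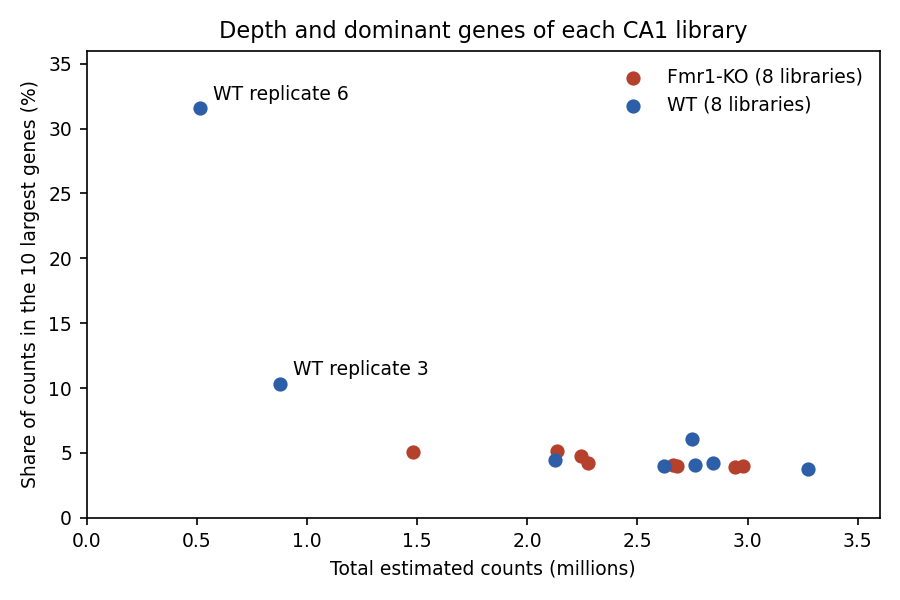
Total estimated counts (horizontal axis) and the percentage of counts in the 10 largest genes (vertical axis) for each of the 16 CA1 libraries, 1 point per library, coloured by genotype. WT replicate 6, at 31.59%, and WT replicate 3, at 10.35%, lie apart from the other libraries.

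Fmr1 itself, the targeted gene, was lower in all 8 Fmr1-KO libraries than in any WT library, which matches the labels. Its level was 22.2 ± 7.08 CPM in Fmr1-KO and 58.1 ± 19.4 CPM in WT (SD, n = 8 each), a 2.65-fold fall on chromosome X at 68678541 to 68717963 (GRCm38, ENSMUSG00000000838). The log2 fold change was −1.41 (SE 0.22), with an adjusted p of 0.0112 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Fmr1 RNA therefore remained detectable in the knockout, from 8.44 to 32.0 CPM. By the deposited assignment of reads to transcripts, the fall lay in the protein-coding ones. These went from 52.2 ± 16.7 CPM in WT to 15.1 ± 4.87 CPM in Fmr1-KO (exact permutation test, two-sided p = 0.000155, the smallest it can give). The other Fmr1 transcripts, among them those annotated as retaining an intron, stood at 5.87 ± 5.35 CPM in WT and 7.10 ± 3.39 CPM in Fmr1-KO (exact permutation p = 0.586). In TPM, whose scale depends on the effective lengths of each library, Fmr1 averaged 24.4 ± 13.8 in WT and 16.7 ± 6.27 in Fmr1-KO and the difference did not pass (exact permutation p = 0.167). Without WT replicates 3 and 6 the WT mean was 29.9 ± 10.97 TPM (n = 6, exact permutation p = 0.018, chosen after seeing the depths).

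The larger of the 2 differences past the threshold was that of Ccnd2, which encodes cyclin D2, a regulator of entry into the cell cycle that is also needed for the birth of hippocampal neurons. Ccnd2 fell 7.16-fold, from 41.2 ± 10.3 CPM in WT to 5.73 ± 2.57 CPM in Fmr1-KO (SD, n = 8 each), and was lower in all 8 Fmr1-KO libraries than in any WT library. Kcnt1, which did not pass, was likewise lower in every Fmr1-KO library than in any WT library, so such separation alone does not set Ccnd2 apart. Ccnd2 lies on chromosome 6 at 127125162 to 127152193 (GRCm38, ENSMUSG00000000184). Its log2 fold change was −2.84 (SE 0.27), with an adjusted p of 4.07e-06 in the edgeR test with Benjamini-Hochberg adjustment. The other D-type cyclins did not pass that test. Ccnd1 stood at 113 ± 24.3 CPM in WT and 89.3 ± 13.6 CPM in Fmr1-KO, and Ccnd3 at 21.8 ± 10.6 and 31.3 ± 6.63 CPM, both looked up after the Ccnd2 result was seen. The Ccnd2 log2 fold change was −2.90, −3.48 and −2.69 in fits of log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 1) without a filter, relative to the median of all genes, and did not pass there (limma adjusted p = 0.538, 0.530 and 0.625). In filtered log2(TPM + 1) without WT replicates 3 and 6, Ccnd2 passed.

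Ccnd2 and Fmr1 were the only genes past the threshold among 11515 tested, both lower in Fmr1-KO, and 0 genes rose. At an unadjusted p under 0.05 there were 909 genes, 416 higher and 493 lower, where chance alone would give about 576. With libraries scaled by their totals the split was 419 higher and 348 lower. Without WT replicates 3 and 6, 2 of 11866 genes passed, and both were shared with the full set. DESeq2 called 6 genes, 1 of them higher, and limma-voom with quality weights called 7, 2 of them higher. The 3 fits of TPM called 0 genes, with 1047, 960 and 1380 at an unadjusted p under 0.05, and length-scaled TPM counts called 1, Ccnd2, so that Fmr1 did not pass in these 4.

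The genes next in rank did not pass the edgeR test. Kcnt1, a sodium-activated potassium channel whose protein binds FMRP, stood at 53.0 ± 14.7 CPM in WT and 22.7 ± 8.83 CPM in Fmr1-KO, a log2 fold change of −1.22 (SE 0.22, adjusted p = 0.0719 by edgeR). It passed in DESeq2 with and without WT replicates 3 and 6, and in limma-voom with quality weights or with the animal number as a random effect. In edgeR it passed with no filter, with the letter of the animal label as a covariate, at a threshold of 0.1, and without Fmr1-KO replicate 1 (adjusted p = 0.0373). It did not pass in 25 other settings, among them the fits of TPM and edgeR without WT replicates 3 and 6 (adjusted p = 0.110). Efcab6, an EF-hand protein gene, had a log2 fold change of −1.50 (adjusted p = 0.422 by edgeR) and Slc29a4, a monoamine transporter gene, one of −1.50 (adjusted p = 0.506 by edgeR). Efcab6 passed in DESeq2 and in limma-voom with quality weights. On the higher side Arel1, a ubiquitin ligase gene, had a log2 fold change of 0.38 (adjusted p = 0.234 by edgeR) and passed in DESeq2 and in limma-voom with quality weights. Apc2 (0.41), the clock gene Cry2 (0.43), the RNA polymerase III factor Brf1 (0.57) and Sidt1 (0.47) each had an adjusted p of 0.506 in edgeR, and of these Cry2 passed in limma-voom with quality weights and in DESeq2 without WT replicates 3 and 6. For each of these 8 genes, all 8 Fmr1-KO libraries lay on the same side of the WT median. Their choice by smallest p from these same libraries makes that likely, so it adds no support.

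**Figure D2:**
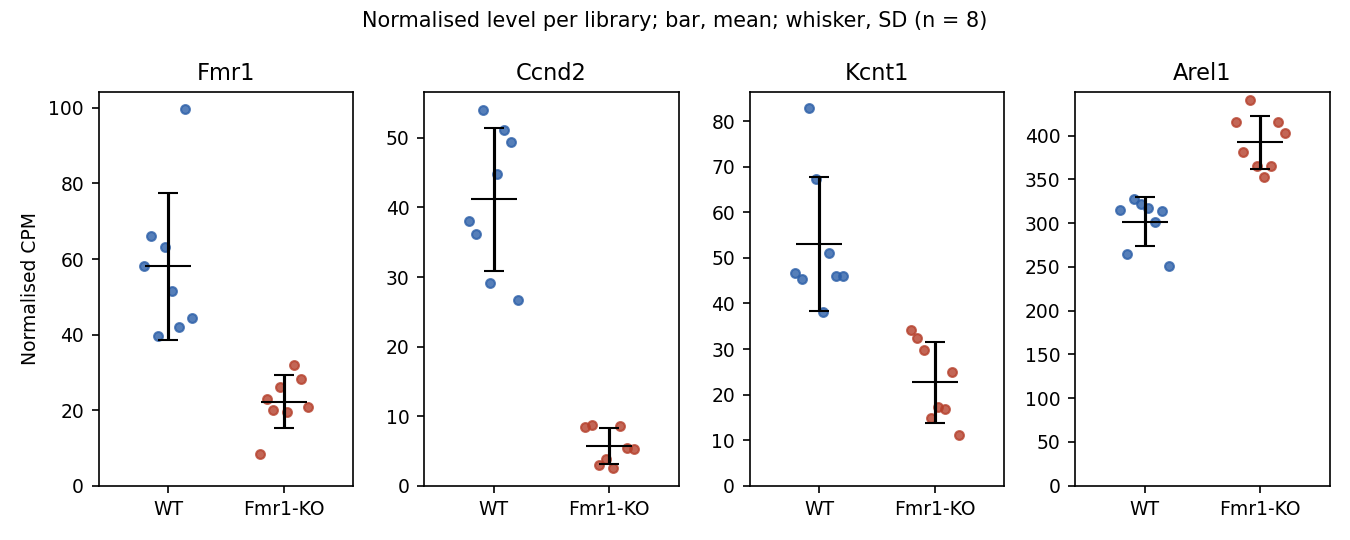
Normalised CPM (vertical axis, from 0) of Fmr1, Ccnd2, Kcnt1 and Arel1 in each library, with the mean (bar) and SD (whisker) of 8 WT and 8 Fmr1-KO libraries. Fmr1 and Ccnd2 passed the edgeR test, while Kcnt1 and Arel1 did not pass. The groups did not overlap for any gene shown.

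At the level of transcripts, 1 of 16772 tested passed, the protein-coding Ccnd2-001, which fell by 2.88 on the log2 scale (SE 0.30, adjusted p = 0.000563 by edgeR with Benjamini-Hochberg adjustment). It went from 40.6 ± 10.3 to 5.45 ± 2.37 CPM. At an unadjusted p under 0.05 there were 655 transcripts. Of the Fmr1 transcripts, the protein-coding Fmr1-006 had a log2 fold change of −1.57 (SE 0.88) and did not pass. The tested transcript of Efcab6, Efcab6-003, is annotated as a processed transcript, not as protein-coding (19.0 CPM in WT, 6.15 in Fmr1-KO). For Kcnt1, Kcnt1-008, annotated as retaining an intron, went from 22.3 to 10.5 CPM and the protein-coding Kcnt1-001 from 11.7 to 3.96 CPM. None of these passed.

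The segment around the targeted locus was examined because a knockout allele can carry flanking sequence of another strain. Within 10 Mb of Fmr1, 0 of 67 tested genes passed the edgeR test, and 6 had an unadjusted p under 0.05. That share of 8.96% compared with 7.88% of the 11447 other genes (Fisher exact test, two-sided p = 0.651). Only 1 of those other genes passed the edgeR test, so the count of 0 near Fmr1 could hardly differ. The share was 12% of 25 genes within 5 Mb and 11.5% of 96 within 20 Mb. Neither differed from the other genes, at 7.88% and 7.86% (Fisher exact test, p = 0.443 and 0.183).

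Groups of genes shifted by small amounts without their members passing singly. Of 541 genes in the 20 lists, Fmr1 alone passed over all genes, while 75 had an unadjusted p under 0.05, 38 higher and 37 lower. In camera, 8 lists passed the threshold, 2 toward higher and 6 toward lower levels in Fmr1-KO. With an estimated inter-gene correlation 0 of the 20 passed, and the smallest adjusted p was 0.0887, for cholesterol synthesis. With fry 0 of the 20 passed. These 8 calls therefore depend on the preset correlation. Markers of endothelium and pericytes, microglia and oligodendrocytes were lower in the same comparison (medians −0.66, −0.39 and −0.40), and both shallow libraries were WT.

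The mRNAs reported to be bound by FMRP rose slightly as a list. Of 100 tested, 81 were higher and 19 lower, with a median log2 fold change of 0.12 (camera adjusted p = 9.39e-06, but adjusted p = 0.599 with an estimated correlation). None of the 100 passed over all genes, and 18 had an unadjusted p under 0.05, 15 of them higher. Adjusted over the list alone, 1 passed, Kcnt1, which went against the list. Grin1, the obligatory NMDA receptor subunit, stood at 1251 ± 175 CPM in WT and 1528 ± 66.7 CPM in Fmr1-KO (log2 fold change 0.29). The neurite protein gene Ncdn had a log2 fold change of 0.18, and the scaffold gene Dlgap3 one of −0.34. Random lists matched on length, GC content and abundance had a median of 0.11.

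The immediate early genes, which neurons transcribe within minutes of activity, also rose as a list. Of 28, 25 were higher, with a median log2 fold change of 0.25 (camera adjusted p = 0.000494, but adjusted p = 0.599 with an estimated correlation). Adjusted over the list alone, 0 passed, and 2 had an unadjusted p under 0.05, Rgs2 (0.47) and the nuclear receptor gene Nr4a3 (0.30). The activity-dependent transcription factor genes Npas4 (0.79, SE 0.43) and Fosb (0.58, SE 0.31) varied widely between animals. Random lists matched on length, GC content and abundance had a median of 0.01, and the list lay at percentile 100 of them. Such lists do not share the correlation of co-regulated genes, so that percentile overstates the separation. The median of the immediate early genes was 0.18 without WT replicates 3 and 6.

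Genes of protein synthesis and respiration were lower. Of 75 cytosolic ribosomal protein genes, 72 were lower, with a median log2 fold change of −0.20 (camera adjusted p = 1.75e-06, but adjusted p = 0.599 with an estimated correlation). Examples were Rps16 (−0.70) and Rpl11 (−0.55), neither of which passed. Of 71 nuclear genes of oxidative phosphorylation, 62 were lower, with a median of −0.21 (camera adjusted p = 0.000174, but adjusted p = 0.673 with an estimated correlation), among them Atp5e (−0.65) and Cox7a2 (−0.58). All 13 mitochondrially encoded protein genes were lower, with a median of −0.26 (camera adjusted p = 0.000208, but adjusted p = 0.599 with an estimated correlation), including mt-Nd4 (−0.30) and mt-Cytb (−0.33). In these 3 lists 0 genes passed over all genes or adjusted over the list alone, while 6, 3 and 3 had an unadjusted p under 0.05, each lower. Random lists matched on length, GC content and abundance had a median of −0.13 for the first 2 of them and −0.08 for the mitochondrially encoded genes, whose own median lay at percentile 4.65 of these lists, inside their central 95%, and at percentile 1.69, outside it, without WT replicates 3 and 6. The medians were −0.26, −0.28 and −0.14 without WT replicates 3 and 6, where mt-Nd4 had −0.14 and mt-Cytb −0.21, and the 3 lists still passed.

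The cholesterol synthesis list was lower, with 17 of 21 genes lower and a median of −0.20 (camera adjusted p = 0.000673, adjusted p = 0.0887 with an estimated correlation). Idi1 had a log2 fold change of −0.68 and Sqle of −0.43, and 0 of the 21 passed adjusted over the list alone. The median was −0.13 without WT replicates 3 and 6. It lay at percentile 0.81 of the matched random lists, and at 2.10 without those libraries. Heat shock and chaperone genes were lower in 19 of 24 (median −0.08, camera adjusted p = 0.0218, but adjusted p = 0.599 with an estimated correlation). Adjusted over the list alone, 2 of them passed, the stress-response transcription factor gene Xbp1 (−0.62) and Sdf2l1 (−1.26), an endoplasmic reticulum protein gene. Hspa1b had −0.54. That list lost its call without Fmr1-KO replicate 1, 2 or 8 or WT replicate 1, 2, 7 or 8 (adjusted p up to 0.129) and with libraries scaled by their totals (median −0.04, adjusted p = 0.0534), and its median was −0.15 without WT replicates 3 and 6. It lay at percentile 0.24 of the matched random lists. Of the 17 genes listed for reactive glia and complement, only 8 were tested. That list was lower in 7 of 8 (median −0.46, camera adjusted p = 0.0112, but adjusted p = 0.219 with an estimated correlation). Serpina3n (−0.55) passed adjusted over the list alone, and Gfap had −0.46, or −0.07 without WT replicates 3 and 6. The median of the list was −0.09 and its camera adjusted p 0.068 without WT replicates 3 and 6, and the adjusted p was 0.0678 without WT replicate 3 alone. The list lay at percentile 0.06 of the matched random lists, and at 34.09 without WT replicates 3 and 6.

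The remaining 12 lists did not pass camera. Synaptic and channel genes had small positive medians, 0.08 for glutamate receptors, 0.07 for GABA receptors (0.03 without WT replicates 3 and 6), 0.09 for calcium channels, 0.06 for potassium and HCN channels, 0.10 for sodium channels, 0.06 for postsynaptic scaffolds and 0.05 for vesicle release, with camera adjusted p from 0.149 to 0.646. The glutamate receptor median was 0.03 with 1 CPM in 8 libraries. With libraries scaled by their totals the medians were 0.11 for GABA receptors, 0.10 for potassium and HCN channels, 0.11 for postsynaptic scaffolds and 0.10 for vesicle release. Adjusted over the list alone, 1 glutamate receptor gene passed (Grin1), 1 calcium channel gene (Cacna1g, a T-type channel, −0.77, which passed in limma-voom with quality weights) and 1 potassium channel gene (Kcnt1). Of the other members, Gria3 had 0.29, Gabra3 −0.46, Cacna1b 0.31, Kcnj9 0.37, the leak channel gene Kcnk2 −0.39, Scn8a 0.25, Homer2 0.30, Camk2b 0.17, Napb 0.21 and Syt1 0.22. The kainate receptor gene Grik4 had −1.45 over all libraries and −0.10 without WT replicates 3 and 6. FMRP and its partners had a median of 0.04 with 1 gene past the threshold (Fmr1), also the 1 that passed adjusted over the list alone, and Cyfip2 had 0.19, or 0.12 without WT replicates 3 and 6. PI3K and mTOR genes had a median of −0.03, which turned to 0.02 when libraries were scaled by their totals and to 0.01 without WT replicates 3 and 6, with Tsc2 at 0.25, or 0.14 without them. The endocannabinoid list had 0.04, or 0.01 without WT replicates 3 and 6 (Mgll −0.28), the glucocorticoid-responsive list 0.05, or −0.02 without WT replicates 3 and 6 (Sgk1 0.46, Zbtb16 0.36), and the circadian clock list 0.03 (Bhlhe40 −0.24, Dbp −0.50), in which Cry2 passed adjusted over the list alone. For FMRP and partners, glutamate receptors, GABA receptors, potassium channels and the clock genes, the mean log2 fold change was negative while the median was positive, and camera pointed lower for FMRP and partners, the endocannabinoid list and the clock genes despite their positive medians.

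Markers of several cell types other than CA1 pyramidal neurons were lower in Fmr1-KO. Of 13 marker lists, 7 passed camera, each toward lower levels, while 0 of the 90 marker genes passed over all genes and 15 had an unadjusted p under 0.05, 14 of them lower. All 11 endothelial and pericyte markers were lower (median −0.66, camera adjusted p = 4.03e-05, but adjusted p = 0.163 with an estimated correlation), among them the tight junction gene Cldn5 (−1.21) and Itm2a (−0.66). Without WT replicates 3 and 6, Pecam1 turned from −1.21 to 0.17, while Cldn5 had −1.10, Itm2a −0.58 and Vtn −0.40. All 10 microglial markers were lower (median −0.39, camera adjusted p = 0.0085, but adjusted p = 0.362 with an estimated correlation), among them the complement gene C1qa (−0.42). All 10 oligodendrocyte markers were lower (median −0.40, camera adjusted p = 0.0275, but adjusted p = 0.425 with an estimated correlation), including the myelin genes Mobp (−0.43) and Mbp (−0.34). The other 4 were markers of oligodendrocyte precursors (median −0.45), astrocytes (−0.28, with Aqp4 at −0.62), GABAergic interneurons (−0.19) and the subiculum and neighbouring cortex (−0.63). Their camera adjusted p ran from 0.0431 to 0.0437, and with an estimated correlation the adjusted p was 0.362, 0.425, 0.425 and 0.163. Fn1, a subicular marker, had −0.77 and passed adjusted over the list alone. Without WT replicates 3 and 6, 3 of the 7 lists passed, those of oligodendrocytes (median −0.37), microglia (−0.23) and endothelium and pericytes (−0.38). The medians of the other 4 were then −0.07 for oligodendrocyte precursors, −0.10 for astrocytes, −0.05 for GABAergic interneurons and −0.27 for the subiculum and cortex, with Aqp4 at −0.22 and Fn1 at −0.47. The number of marker lists past the threshold was 2 without Fmr1-KO replicate 5 or 8, 3 without Fmr1-KO replicate 6 or WT replicate 5, and 4 without Fmr1-KO replicate 7 or WT replicate 3, 6 or 8. The 4 without WT replicate 3 include the CA3 list (adjusted p = 0.0427). The oligodendrocyte call was lost without Fmr1-KO replicate 5, 6 or 8 or WT replicate 5 or 8 (camera adjusted p up to 0.0951). The microglia call was lost without WT replicate 3 (camera adjusted p = 0.0943). That of endothelium and pericytes held with each of the 16 libraries left out in turn.

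CA1 pyramidal markers themselves did not pass (8 genes, median −0.05, camera adjusted p = 0.804). Fibcd1 had 0.22 and passed adjusted over the list alone. The median turned to 0.01 with libraries scaled by their totals and was −0.01 without WT replicates 3 and 6. The CA3 (median −0.40), dentate granule (−0.64), thalamus (−0.37), red blood cell (−0.42) and sex-linked (−0.01, with a mean of 0.01) lists, of 3 or 4 tested genes each, did not pass either, except CA3 without WT replicate 3 (adjusted p = 0.0427). Only 3 of 7 listed genes were tested for CA3, 4 of 9 for dentate granule cells, 3 of 6 for thalamus and 3 of 5 for red blood cells. The dentate median was −0.30 with 1 CPM in 8 libraries, and the sign of the sex-linked median turned with libraries scaled by their totals. Without WT replicates 3 and 6 the medians were −0.12 for CA3, 0.06 for dentate granule cells, −0.06 for thalamus, −0.65 for red blood cells and −0.10 for the sex-linked list.

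**Figure D3:**
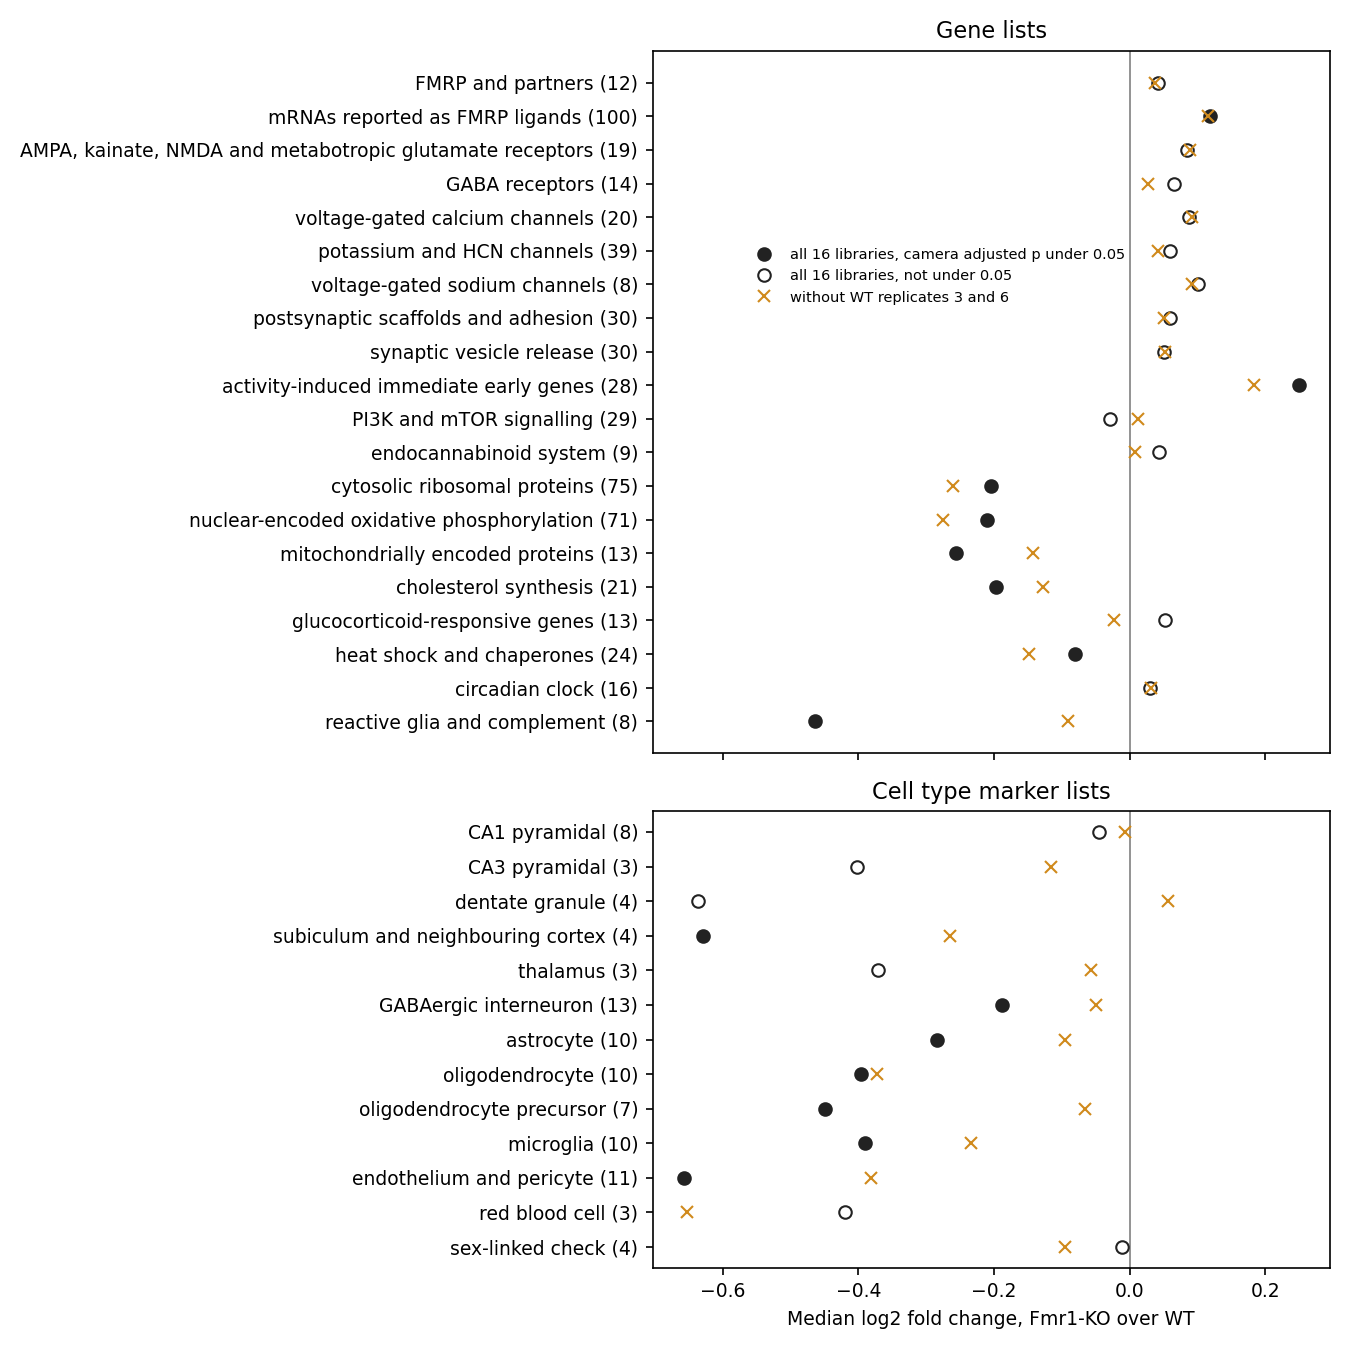
Median log2 fold change, Fmr1-KO over WT (horizontal axis), of the tested genes of each gene list and cell type marker list (vertical axis, number of tested genes in brackets). Circles show all 16 libraries, filled where the camera adjusted p was under 0.05, and crosses show the medians without WT replicates 3 and 6. Ribosomal and oxidative phosphorylation lists kept their shift, at −0.26 and −0.28, while reactive glia moved from −0.46 to −0.09.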

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

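Extreme libraries were sought in 30 groups of 8 values (library measures and the first-named genes, in both genotypes) by the gap to the nearest library relative to the range of the group. Of these 6 stood out, where chance gives about 1 in 20, and each was a WT library. In WT replicate 6 the 10 largest genes took 31.59% of the counts, against 3.73% to 10.35% in the other WT libraries. In the same library protein-coding transcripts held 58.38% of the counts, against 80.67% to 91.75%. Fmr1 reached 99.7 CPM in WT replicate 7, against 39.6 to 66.0 CPM. Apc2 reached 276 CPM in WT replicate 5, against 176 to 211 CPM, which lies within the Fmr1-KO values. Brf1 reached 57.4 CPM in WT replicate 8, against 31.0 to 43.0 CPM. Efcab6 reached 43.2 CPM in WT replicate 3, against 11.4 to 25.5 CPM.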

How the results depend on the processing

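The settings without WT replicates 3 and 6 and the marker alternatives were chosen after seeing the data. The 2 genes called by edgeR also passed with DESeq2 size factors, library totals, 1 CPM in 8 libraries, the letter or number of the animal label, 1 surrogate variable, a threshold of 0.1 and each library left out in turn (2 to 3 genes). Kcnt1 was the gene gained with the letter, the number, the threshold of 0.1 and without Fmr1-KO replicate 1. More genes passed with DESeq2 (6), no filter (5), voom quality weights (7) and DESeq2 without WT replicates 3 and 6 (6), and the 2 genes were among them each time. Gm14033 passed with DESeq2, and Gm13568 and Gm28437 with no filter, named after their values were seen. Fewer passed with length-scaled TPM counts (1, Ccnd2), log2(TPM + 1) (0), log2(TPM + 0.1) (0), log2(TPM + 1) without a filter (0) and log2(TPM + 1) without both libraries (1, Ccnd2). Those settings gave 1047, 960, 1380 and 665 genes at an unadjusted p under 0.05 for the 4 TPM fits and 894 for the scaled counts. With all 16 libraries the TPM fits moved the median of all genes by 0.48, 0.60 and 0.27 (log2), and changes are given relative to it. The Fmr1 level then fell short of the threshold, at −0.87, −0.99, −0.65, −0.81 without both libraries and −1.01 with scaled counts (adjusted p 0.597, 0.618, 0.626, 0.958 and 0.569), and Ccnd2 did in the 3 fits of all libraries. Without both libraries the median of all genes in log2(TPM + 1) moved by 0.07, and Ccnd2 passed while Fmr1 did not. The loss of the Ccnd2 call in filtered log2(TPM + 1) thus depended on those libraries. The cause was not tested otherwise. In log2(TPM + 1) without a filter the Dlgap3 log2 fold change (0.0161), Mgll log2 fold change (0.0592), mt-Nd4 log2 fold change (0.0886), mt-Cytb log2 fold change (0.0619), and Gfap log2 fold change (0.103) reversed, and in filtered log2(TPM + 1) without both libraries the Grik4 log2 fold change (0.12) and that of Gfap (0.0782) did, none past a threshold. Transcripts past the threshold numbered 1 to 2 with a library left out, 2 without Fmr1-KO replicate 2, 7 or 8 or WT replicate 5. Gene lists fell to 0 with an estimated correlation and 0 with fry, and stood at 7 to 8 otherwise. Marker lists fell to 0 and 0 likewise, to 4 with 1 CPM in 8 libraries, to 3 without both libraries, and to 2 to 7 with a library left out, the lowest without Fmr1-KO replicate 5 or 8, 3 without Fmr1-KO 6 or WT 5, and 4 without Fmr1-KO 7 or WT 3, 6 or 8. Astrocyte markers moved to an adjusted p of 0.701 and microglia to 0.0943 without WT replicate 3, and reactive glia to 0.0678. No paired analysis was possible because the labels share no animal number between genotypes. At the depth, spread and number of these libraries 28.4% of simulated 1.5-fold changes were recovered. Many genes were changed together there, so recovery would be lower where few genes change.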

Other observations

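The tests on the 2 shallow WT libraries, on neighbours of Ccnd2 and on the biotype of Fmr1 reads, the count of splits without Fmr1 and the pool of genes for the matched lists were chosen only after the result was seen.

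A pair of transcripts of Chd3, a chromatin remodeller gene reported to be bound by FMRP, stood near the top of the transcript ranking and was noticed after its values were seen. Chd3-004 stood at 93.5 ± 102 CPM in WT and 1.93 ± 3.80 CPM in Fmr1-KO, while Chd3-201 stood at 17.7 ± 14.9 and 82.4 ± 24.4 CPM (SD, n = 8 each). Neither passed the edgeR test with Benjamini-Hochberg adjustment (adjusted p = 0.304 for Chd3-004 and 0.9999 for Chd3-201). The estimates share reads between the transcripts, and Chd3-004 varied widely among WT animals.

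Whether other splits of the 16 libraries into 8 and 8 gave as many calls was counted over 100 splits, the real one included. For genes, 1 split, the real one, gave 2, the highest other being 1, though 1 of the 2 is Fmr1, the targeted gene. The count was therefore repeated without Fmr1, and 2 splits gave at least 1, the highest other being 1. So small a share of 100 splits makes chance less likely but does not exclude it. For transcripts 3 splits gave at least 1, the highest other being 1, which also makes chance less likely, though the count is small. For the marker lists at the preset correlation 2 splits gave at least 7, the highest other being 7. That makes chance less likely for that count only. With an estimated correlation or fry 0 marker lists passed, the smallest adjusted p being 0.163 and 0.159, and 3 passed without WT replicates 3 and 6. For the gene lists chance stays open, because 5 splits gave at least 8 and the highest other gave 11. The 909 genes at an unadjusted p under 0.05 were matched or passed by 8 splits, with up to 1510. The highest counts, 11 lists and 1510 genes, came from splits with WT replicates 3 and 6 on one side, as in the real split. With them on different sides the highest were 8 lists and 1206 genes. The median among the other splits was 4 lists either way. For the unadjusted genes it was 509 with them on one side and 352 with them on different sides. Marker lists reached at most 5 among the other splits with both on one side, and 7 among those with them on different sides.

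The lower Ccnd2 was weighed against 4 explanations. Reads moved to another D-type cyclin would leave the sum alike. Ccnd1, Ccnd2 and Ccnd3 together instead changed by −0.48 on the log2 scale (exact permutation p = 0.000311). Part of that was Ccnd1 itself, which changed by −23.4 CPM (exact permutation p = 0.0266). Ccnd3 changed by 9.51 CPM (exact permutation p = 0.0513), a smaller amount than the −35.5 CPM of Ccnd2. The 2 shallow WT libraries do not carry the Ccnd2 fall, which was −2.73 on the log2 scale without them. A linked segment of another strain on chromosome 6 cannot be told apart from an effect of genotype, because 3.51% of the 57 genes within 5 Mb had an unadjusted p under 0.05 against 7.89% elsewhere (Fisher exact p = 0.322), and a segment could alter Ccnd2 alone. For fewer dividing cells or newborn neurons, the 10 tested markers had a median of −0.11 (bootstrap SE 0.13), 7 of them lower. The lowest was Sox11 at −0.71, so none fell as far as Ccnd2. That median met the bar first set for excluding such a loss. The explanation is kept open under the raised bar, because 7 of the 17 markers were not tested and Tubb3, at 125 CPM in WT, has a high baseline. A difference in ancestry between the colonies and an effect of FMRP loss both stay open and untested, so a genotype effect on Ccnd2 is a hypothesis only.

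Of the Fmr1 counts left in the knockout, 68.8% were assigned to protein-coding transcripts, against 92.0% in WT. Taken as it stands, that assignment does not leave transcripts retaining an intron as the only source. It is a model estimate between transcripts that can share sequence, from 305 protein-coding and 139 other counts over the Fmr1-KO libraries, so it cannot decide the question. The remaining reads may come from an allele that still transcribes part of the gene, which gene-level estimates cannot locate within the exons.

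The fold changes of all genes followed transcript length, with medians from −0.12 in the shortest of 5 length groups of genes to 0.05 in the longest, a trend across genes, which are not independent replicates. Against 10000 random lists matched on length, GC content and abundance, the FMRP ligand median of 0.12 lay at percentile 78.83, where the matched lists had a median of 0.11, so the higher level of these long mRNAs may reflect that trend. The ribosomal median of −0.20 lay at percentile 0.63 and the oxidative phosphorylation median of −0.21 at percentile 1.19, where matched lists already had −0.13 each, so length, GC content and abundance leave a remainder. The ribosomal median was −0.26 without WT replicates 3 and 6, which argues against the shallow libraries. What stays open is RNA integrity or library preparation differing between the genotypes, for which the labels give no value, and random lists do not share the correlation of co-regulated genes, so these percentiles overstate the separation.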
